A study of Oryza sativa Japonica Group with 9 samples.

How the data were processed

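Gene expression was measured on 9 single-colour rice arrays of laser-captured cortical root cells, each from about 2000 captured cells. Rice of the japonica cultivar Nipponbare was harvested at 7 weeks. The inoculated plants had received 250 spores of Rhizophagus irregularis, an arbuscular mycorrhizal fungus, at planting. The 3 groups of 3 arrays were arbusculated cells, which held the branched fungal structures called arbuscules, systemic cells, which were free of the fungus but lay beside arbusculated cells in colonised roots, and mock cells from roots given no fungus.

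The authors deposited log2 values per probe set, made with RMA, which corrects background, normalises quantiles and summarises the probes of a set. The RMA version, the software around it and the probe definition are not given in the sources used here. The deposited log2 values ran from 1.52 to 14.06 and were used as they stood. For arrays the number per group, 3, limits the precision.

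Of 57381 probe sets, 123 array controls were left out and 57258 were tested. The reference tables paired 22436 probe sets with exactly 1 gene, 95 with several and 34727 with none. They held 17905 genes with a probe set, of which 2456 had an informative name. Gene neighbours, among genes with a probe set, were read from the annotation of assembly ASM3414082v1.

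The comparisons were fitted with limma 3.58.1 in R 4.3.3, with all 9 arrays in 1 linear model and moderated variances, tests open to both directions and Benjamini-Hochberg adjustment within each contrast at 0.05. The contrasts were arbusculated against mock, systemic against mock and arbusculated against systemic. A moderated F test covered any difference among the 3 groups. A further count took probe sets past the threshold and higher in arbusculated cells than in both other groups.

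A gene was represented by the probe set with the highest mean over all 9 arrays among those paired with it alone. The genes named were, in each contrast, the 10 largest rises and the 10 largest falls past the threshold, or all if fewer, among representatives with an informative name, groups that did not overlap and no suffix for cross-hybridising probe sets (_x_at). Every measured member of the mycorrhiza marker list and of the PHT1 phosphate transporter list was also named, and of every other list up to 4 members past the threshold, at most 2 per direction. Features named outside this rule, among them the members given as examples of a list, were chosen after their values were seen.

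The 13 gene lists fixed by identifiers held 97 members. Of these 52 were measured, 31 had a name missing from the tables, 11 had no probe set of their own, and 3 were left out because their name in the tables went against their identifier. The 8 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01. They were PHT1 phosphate transporters, symbiosis signalling, phosphate starvation response, strigolactone and apocarotenoid synthesis, nitrogen transport and assimilation, metal acquisition, and markers of endodermis and of xylem and sclerenchyma. The 29 lists defined by words in product names were not tested, since the tables gave no product names. In their place 31 lists were written from gene symbols after the tables were seen and before any comparison was computed, and 30 of them could be tested. An error in matching symbols to genes was corrected after a first run of the list tests had been seen, and the counts before the correction are kept as an alternative. Camera with an estimated correlation and the direction test of fry were alternatives for every list. Camera sets the members of a list against all other genes, so the direction it gives is relative to those genes. A list can thus point down although the mean or median of its own changes is above 0, and up although it is below.

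The 3' minus 5' difference of 7 pairs of rice control probe sets gave a measure of RNA quality per array. Deviations from the group means were compared between arrays with the same replicate number. Their correlations ran from -0.285 to 0.0388, and 0 of 3 pairs passed 0.1 in any of the contrasts. The replicate numbers were not used as pairs, since they are not stated to mark shared plants. Nothing in the labels states that replicates came from separate plants, so the p-values measure only the spread between samples.

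The groups, contrasts, thresholds, identifier lists, naming rule and all alternatives but those named as added were fixed before the data were examined. The alternatives were variance moderation with trend and robust fitting, removal of dim or cross-hybridising probe sets, centring of each array, a further quantile normalisation, fits to the 6 arrays of a contrast, array weights, a replicate block, the mean of all probe sets of a gene, a 2-fold threshold, and leaving out each array in turn. Cyclic loess normalisation, the lists from gene symbols and the matching before its correction were added after the data had been seen, and the lists with the responding probe set of PT11 and random lists matched for level after the results had been seen.

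The pipeline was tested on simulated data with 50 changed probe sets at each size. For arbusculated against mock it recovered 1 at a log2 change of 1, 27 at 2, 43 at 3 and 49 at 5, with 8 false calls. For arbusculated against systemic it recovered 0, 29, 41 and 48 of 50 at the same sizes, with 6 false calls. The list test called 1 of 1 raised list and 0 of 10 unchanged lists. The simulated genes varied independently, so this cannot show how often lists of genes that vary together are called falsely. Each count was also compared with other splits of the arrays, all 10 for a contrast and 100 drawn for the 3 groups.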

Results

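Transcript levels in cortical cells of rice roots were measured on 9 arrays, 3 each for arbusculated, systemic and mock cells, and 57258 rice probe sets were compared. The median log2 value per array lay between 5.42 and 5.54. The array of mock replicate 2 had a mean correlation of 0.878 with the arbusculated arrays and 0.853 with the other mock arrays (0.836 with mock 1 and 0.870 with mock 3), across probe sets, which are not independent. The 3' minus 5' difference of the rice controls, a measure of RNA quality, was 0.78 ± 0.45 (SD, n = 3) in arbusculated, 0.32 ± 0.11 in mock and 0.20 ± 0.32 in systemic cells. The labels do not tie samples to plants. If samples of a group shared plants, p-values over them would be too small, and whether arbusculated and systemic cells came from the same plants is not given in the sources used here.

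Arbusculated against mock cells asks which transcripts differ in a cortical cell that houses the fungus. ILL8 (LOC4342839), an ILR1-like hydrolase of auxin conjugates, rose 8.95-fold, by 3.16 ± 0.24 (log2, SE; n = 3 per group; adjusted p = 0.00399 by limma). DXR (LOC4326153), the reductoisomerase of the plastid pathway of isoprenoid synthesis, rose by 2.13 ± 0.27 (adjusted p = 0.0299). YSL13 (LOC4336441), a yellow stripe-like metal transporter, rose by 2.12 ± 0.29 (adjusted p = 0.0387). CKI1 (LOC4330018), a casein kinase I, rose by 2.78 ± 0.34 and HIRL1 by 2.66 ± 0.34, with adjusted p of 0.0273 and 0.0299. Averaging the probe sets of HIRL1 gave 0.95 (adjusted p = 0.41, the highest of its alternatives, which started at 0.0168). PPT1 (LOC4346653) rose by 2.17 ± 0.31 (adjusted p = 0.0445), and no gene with an informative name fell. ILL8 kept its call with any 1 array left out (adjusted p at most 0.0373 over all alternatives), while PPT1 lost it with any array left out (up to 0.156), CKI1 with any but arbusculated 1 (up to 0.106), HIRL1 with any but mock 2 (up to 0.12), DXR with any but systemic 3 (up to 0.129) and YSL13 with any but arbusculated 3 (up to 0.148).

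PT11 (LOC4324187), the phosphate transporter of the membrane around arbuscules, was measured by several probe sets that differed. Its representative probe set differed by -0.33 ± 0.22 without passing the test (adjusted p = 0.469). Another probe set of the gene, chosen after its values were seen, rose by 5.00 ± 0.36 (adjusted p = 0.00303), from 3.88 ± 0.32 (SD) in mock to 8.88 ± 0.57 in arbusculated cells. That rise kept its call with any 1 array left out but did not pass the test when all probe sets of the gene were averaged, at 1.47 (adjusted p = 0.245). The other measured mycorrhiza marker, the ammonium transporter AMT3;1 (LOC4324937), was 1.01 ± 0.32 higher (adjusted p = 0.298).

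Of the 9 measured PHT1 phosphate transporters, 0 rose and 0 fell in any of the contrasts by their representative probe sets in limma. Against mock, PT8 was 2.19 ± 1.33 higher in arbusculated cells (adjusted p = 0.439), PT2 0.95, PT4 0.77 and PT1 0.77 higher. PT6 differed by -1.39, PT7 by -0.65, PT12 by -0.37 and PT3 by -0.30. The list had a median of -0.30, a mean of 0.18 and a test pointing down (adjusted p = 0.609), with 0 members past the threshold adjusted over the list alone. That direction rests on the representative of PT11, at -0.33. With the responding probe set of PT11, an alternative chosen after its values were seen, the median was 0.77 with 5 of 9 higher and the test pointed up (adjusted p = 0.851).

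**Figure D1:**
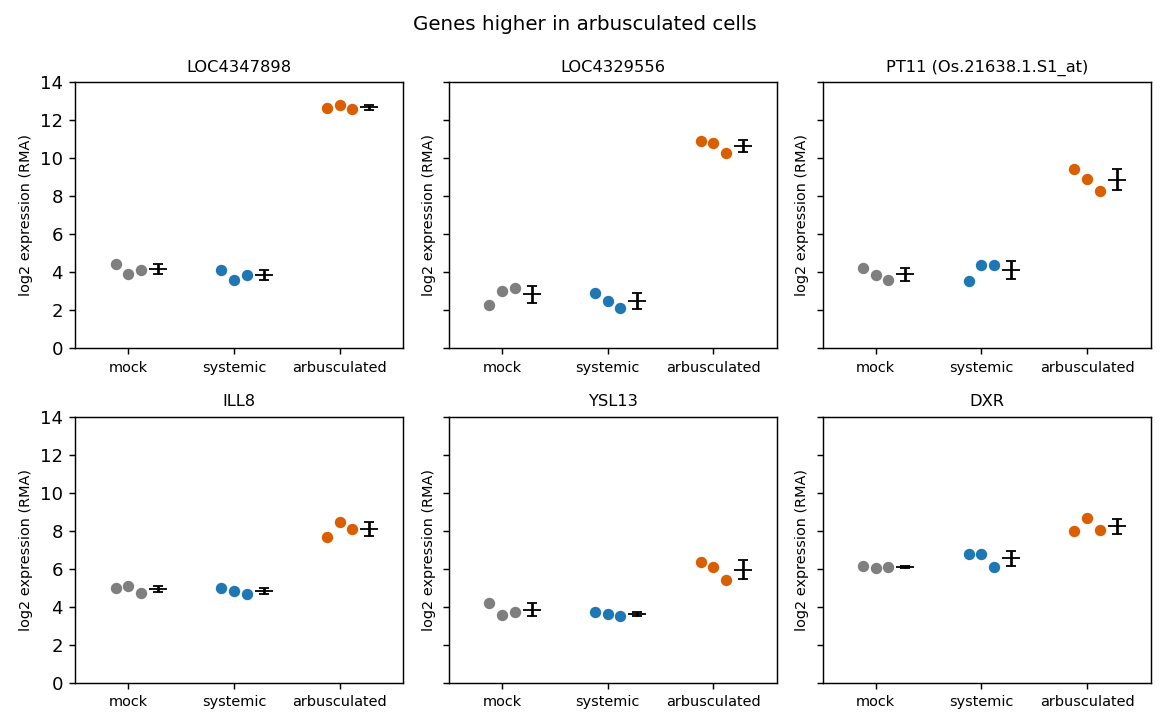
Log2 expression (RMA) on each array, by group, for 6 probe sets higher in arbusculated cells. Coloured points are the 3 arrays of a group and black bars the mean with the SD. For ILL8 the group means are 8.11 in arbusculated, 4.94 in mock and 4.83 in systemic cells.

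The largest rises over mock were in genes without an informative name, and these were chosen after their values were seen. LOC4347898 rose by 8.54 ± 0.23, from 4.14 ± 0.26 (SD) in mock to 12.69 ± 0.13 in arbusculated cells (adjusted p = 5.08e-06). LOC4329556 rose by 7.83, LOC4347897 by 7.63 and LOC4326659 by 5.91, with adjusted p of 6.77e-05, 1.93e-05 and 0.000707, and these genes kept their calls in every alternative run. Of the 5 probe sets that fell, also named after their values were seen, LOC4349605 changed by -3.70 and LOC4342483 by -2.30, and the others, paired with no gene, by -6.70, -5.25 and -3.22. Those others had means of 4.39, 5.86 and 6.6 in arbusculated and 11.09, 11.11 and 9.82 in mock cells. Systemic cells were low too, at 4.77, 6.81 and 6.28, though no probe set passed between systemic and mock cells. LOC4349605 and LOC4342483 had systemic means of 5.26 and 7.47, between those of arbusculated and mock cells. Each of these falls lost its call without mock 3, with adjusted p of 0.137 for LOC4349605 and 0.128 for LOC4342483, and these genes also lost it without any other array but systemic 2 and arbusculated 3, respectively.

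The cell wall marker list of xylem and sclerenchyma, the cellulose synthases of secondary walls, was lower in arbusculated than in mock cells by camera (adjusted p = 0.00312; adjusted p = 0.444 with an estimated correlation). CESA4 (LOC4324625) differed by -1.13 ± 0.33, CESA7 (LOC4348853) by -1.36 ± 0.38 and CESA9 (LOC4347093) by -0.51 ± 0.34. None of the 3 passed the test over all probe sets in limma, and 2 did adjusted over the list alone. A second probe set of CESA4 differed by -0.45 ± 0.24 (adjusted p = 0.401 in limma). Endodermis markers had a median of 0.56 (adjusted p = 0.609), with 0 of 4 past the test.

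The other fixed lists did not pass, and 0 of their members rose or fell in limma. Symbiosis signalling had 8 of 9 genes higher and a median of 0.35, and phosphate starvation response 5 of 5 higher and a median of 0.54, each with adjusted p = 0.609. Strigolactone and apocarotenoid synthesis had a median of 0.78 (adjusted p = 0.633) with 1 of 6 genes past the threshold adjusted over the list alone. Its carotenoid cleavage dioxygenase D17 (LOC4336591), chosen after its values were seen, was 1.76 ± 0.36 higher (adjusted p = 0.144 over all probe sets). Nitrogen transport and assimilation had a median of 0.38 over 6 genes (adjusted p = 0.851). Metal acquisition had a median of 0.03 over 4 genes with a test pointing down (adjusted p = 0.851). In the lists of symbiosis signalling, phosphate starvation response, nitrogen transport, metal acquisition and endodermis, 0 members passed adjusted over the list alone.

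Of the 30 lists drawn from gene symbols, 3 passed camera in arbusculated against mock cells. Ribosomal proteins were higher, 24 of 25 genes with a median of 1.10 (adjusted p = 0.000156; adjusted p = 0.49 with an estimated correlation). Their members RPS4 and RPL7A-2, chosen after their values were seen, were 1.08 and 1.41 higher, 0 of the 25 passed the test in limma, and the 3' minus 5' difference was also higher in arbusculated (0.78) than in mock cells (0.32). Histone H2B genes were higher in 5 of 5, with a median of 1.84 (adjusted p = 0.0181; adjusted p = 0.49 with an estimated correlation) and 0 past the test. Expansins, which loosen cell walls, had a median of -0.15 with 12 of 29 genes higher and 0 past the test (adjusted p = 0.0272; adjusted p = 0.49 with an estimated correlation), and their mean of -0.04 turned to 0.01 after centring each array and to 0.04 after cyclic loess. The call of H2B was lost without arbusculated 2 (adjusted p = 0.081), mock 1 (0.0519) or mock 2 (0.0529), and that of expansins without arbusculated 3 (0.337) or mock 1 (0.273), while that of ribosomal proteins held with any 1 array left out. Random lists matched for level, drawn after the results were seen, had median changes of 0.45 for ribosomal proteins, 0.46 for H2B and 0.15 for expansins. In the list of metal transport 1 of 52 genes rose, YSL13, and in that of carotenoid and strigolactone synthesis 1 of 10, DXR. Neither list passed, with adjusted p of 0.51 and 0.167.

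In all, 107 probe sets passed in arbusculated against mock cells, 102 higher and 5 lower, and all 107 had groups that did not overlap. Of all probe sets 20.7% had such groups, where chance gives 10%. The median change of all probe sets was -0.12, and it was not subtracted from the changes given. The count was 169 without mock replicate 2, 20 without mock 1, 33 without mock 3, 28 without arbusculated 1, 50 without arbusculated 2, 64 without systemic 1 and 71 without systemic 3. It was 32 with a replicate block, 44 with only the 6 arrays of both groups, 66 with probe sets averaged per gene and 67 among the brighter probe sets. The interquartile range of values, a measure of spread, was 2.437, 2.228 and 2.456 on the arbusculated and 2.216, 2.428 and 2.226 on the mock arrays. A further quantile normalisation, which makes the spreads equal, gave 75, with 70 higher and 5 lower. How far unequal spread adds to the share of groups that did not overlap was not tested.

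Arbusculated against systemic cells compares both cell populations of colonised roots. IAA15 (LOC4337971), an Aux/IAA protein of auxin signalling, rose by 3.45 ± 0.41 in arbusculated cells (log2, SE; n = 3 per group; adjusted p = 0.0246). Its means were 7.64 in arbusculated, 5.79 in mock and 4.19 in systemic cells, and over mock it was 1.85 higher (adjusted p = 0.182). ENR (LOC4345286), the enoyl reductase of plastid fatty acid synthesis, rose by 3.35 ± 0.47 (adjusted p = 0.0417). ILL8 rose by 3.27 ± 0.24 (adjusted p = 0.00381), CKI1 by 2.66 ± 0.34 (adjusted p = 0.0304) and YSL13 by 2.33 ± 0.29 (adjusted p = 0.0274). The peroxiredoxin PRXIIC (LOC4325511) rose by 3.10 ± 0.47 (adjusted p = 0.0492) and the casein kinase CKI (LOC4334396) by 1.72 ± 0.26 (adjusted p = 0.0487). Means in arbusculated, mock and systemic cells were 10.78, 8.94 and 7.67 for PRXIIC and 7.58, 6.65 and 5.87 for CKI. CYCH-1 (LOC4334040), a cyclin H, rose by 1.88 ± 0.26 (adjusted p = 0.0392), with means of 6.59 in arbusculated, 6.57 in mock and 4.71 in systemic cells. No gene with an informative name fell. ILL8 kept its call with any 1 array left out (adjusted p at most 0.0438 over all alternatives). PRXIIC was 1.55 higher when its probe sets were averaged (adjusted p = 0.103, within 0.0433 to 0.15 over its alternatives). PRXIIC and CKI lost their calls with any array left out (each up to 0.126), ENR and CYCH-1 with any but mock 1 (each up to 0.121), and CKI1 with any but arbusculated 1 and mock 2 (up to 0.0945). IAA15 lost its call without arbusculated 1, arbusculated 2, mock 3, systemic 1 or systemic 2 (up to 0.0906), and YSL13 without those or systemic 3 (up to 0.0907).

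The responding probe set of PT11 rose by 4.78 over systemic cells (adjusted p = 0.00381), but not when its probe sets were averaged, at 1.18 (adjusted p = 0.206), and the representative differed by -0.51 (adjusted p = 0.205). AMT3;1 was 0.85 ± 0.32 higher (adjusted p = 0.173). Among the PHT1 genes PT8 was 2.68 ± 1.33 higher (adjusted p = 0.247), with 11.10 on the array of systemic replicate 2 against 5.94 and 5.17 on the others, and PT8 passed without that array, at 4.53 (adjusted p = 0.0362). PT4 was 1.67 ± 0.44 higher (adjusted p = 0.126). PT1 differed by 0.07 and PT2 by 0.01, PT3 by -0.46, PT6 by -0.83, PT7 by -0.84 and PT12 by -0.42. The second probe set of CCaMK, the calcium-activated kinase of symbiosis signalling, was chosen after its values were seen and rose by 1.62 (adjusted p = 0.046), where the representative differed by 0.56 (adjusted p = 0.386). The means of that CCaMK probe set were 6.97 in arbusculated, 6.75 in mock and 5.35 in systemic cells, and it differed by 0.23 between arbusculated and mock cells (adjusted p = 0.635). Its call was lost with any array but mock 2 left out (adjusted p up to 0.14). The largest rise without an informative name was again LOC4347898, by 8.84, and the largest fall, chosen after its values were seen, LOC4337135, by -2.41 (adjusted p = 0.046, and up to 0.126 with any 1 array left out, which ended the call).

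None of the 8 fixed lists passed between arbusculated and systemic cells in camera, with adjusted p from 0.535 to 0.955, and 0 lists had an unadjusted p under 0.05. Adjusted over the list alone, 1 gene passed in PHT1, 1 in strigolactone synthesis and 1 in symbiosis signalling, and 0 in the other lists. The chitin receptor kinase CERK1 (LOC4346173) of symbiosis signalling, chosen after its values were seen, was 1.36 ± 0.34 higher (adjusted p = 0.122 over all probe sets). PHT1 had a median of -0.42, or 0.01 with the responding probe set of PT11, a mean of 0.15 and a test pointing down, and metal acquisition a median of 0.08 with a test pointing down.

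Of the 30 lists from gene symbols, 5 passed in this contrast, and 0 of their members did so in limma. With the symbol matching before its correction, which was made after a first run of the list tests had been seen, 2 passed, metallothioneins and photosynthesis, while diterpenoids and expansins (adjusted p of 0.056 each) and jasmonate (0.126) did not. Metallothioneins, small metal-binding proteins, were higher in 7 of 7 genes with a median of 1.98 (adjusted p = 0.0418; adjusted p = 0.608 with an estimated correlation), among them MT4A at 2.62 and MT1B at 1.98, both chosen after their values were seen. Photosynthesis genes were higher in 1 of 11 with a median of -0.98 (adjusted p = 0.0046; adjusted p = 0.601 with an estimated correlation). Genes of diterpenoid phytoalexin synthesis had a median of -0.27 over 15 (adjusted p = 0.0448; adjusted p = 0.601 with an estimated correlation). Jasmonate synthesis and JAZ genes had a median of -0.13 over 35, which was 0.03 after cyclic loess (adjusted p = 0.0448; adjusted p = 0.601 with an estimated correlation). Expansins had a median of -0.17, a mean of 0.09 and a test pointing down relative to all other genes (adjusted p = 0.0448; adjusted p = 0.663 with an estimated correlation). Each of the 5 calls was lost without systemic 2 (adjusted p = 0.0857). Without arbusculated 3 those of metallothioneins (0.106), diterpenoids (0.106), jasmonate (0.124) and expansins (0.462) were lost, without systemic 3 those of diterpenoids, jasmonate and expansins (each 0.0655), without arbusculated 1 that of diterpenoids (0.164) and without arbusculated 2 that of jasmonate (0.0587). Random lists matched for level, drawn after the results were seen, had median changes of 0.76 for metallothioneins, 0.20 for photosynthesis, 0.04 for diterpenoids, 0.30 for jasmonate and 0.20 for expansins. The diterpenoid median of -0.27 lay inside the central range of its random lists, -0.29 to 0.52, and the medians of the other lists lay outside theirs. In the auxin list of Aux/IAA, ARF, GH3 and PIN genes 1 of 57 rose, IAA15. The 3' minus 5' difference was 0.78 in arbusculated and 0.20 in systemic cells.

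In all, 141 probe sets passed between arbusculated and systemic cells, 133 higher and 8 lower, and all 141 had groups that did not overlap, as 32.1% of all probe sets had, where chance gives 10%. The median change of all probe sets was -0.17. The count was 25 without arbusculated 1, 57 without arbusculated 2, 90 without arbusculated 3, 81 without mock 1, 62 without mock 3, 44 without systemic 1, 36 without systemic 2 and 33 without systemic 3. It was 11 with only the 6 arrays of both groups, 14 with a replicate block, 77 with probe sets averaged per gene and 92 with trend and robust moderation. The interquartile range was 2.437, 2.228 and 2.456 on the arbusculated and 2.218, 2.284 and 2.275 on the systemic arrays. A further quantile normalisation, which makes the spreads equal, gave 107, with 102 higher and 5 lower. How far unequal spread adds to the share of 32.1% was not tested.

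Systemic against mock cells asks whether cells beside arbusculated ones differ from cells of roots without the fungus. No probe set passed in limma, 0 of 57258, while 2485 had an unadjusted p under 0.05 and chance gives 2863. PT11 differed by 0.18 ± 0.22, AMT3;1 by 0.16 ± 0.32, PT2 by 0.94 ± 0.43, PT4 by -0.90 ± 0.44, PT1 by 0.69, PT6 by -0.56, PT8 by -0.49, PT7 by 0.18, PT3 by 0.16 and PT12 by 0.05, all with adjusted p of at least 0.969. Groups did not overlap in 10.2% of probe sets, where chance gives 10%. The count was 3 without mock replicate 2, 1 without mock 3 and 1 without arbusculated 1.

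The xylem and sclerenchyma list was lower in systemic than in mock cells as well (median -0.88; adjusted p = 0.016; adjusted p = 0.676 with an estimated correlation), with CESA4 at -1.34 ± 0.33 and CESA7 at -0.88 ± 0.38, and 1 of 3 past the threshold adjusted over the list alone. That call was lost without mock 1, without mock 3, without systemic 1 and when probe sets of a gene were averaged. A second probe set of CESA4 went the other way, at 0.19 ± 0.24 (adjusted p = 0.969 in limma). The other 7 fixed lists had an adjusted p of 0.999, and 0 of their members passed adjusted over the list alone. Endodermis markers and symbiosis signalling had medians of -0.01 and -0.15 with tests pointing up, and phosphate starvation response a median of -0.22, a mean of 0.05 and a test pointing up.

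Among the lists from gene symbols 3 passed between systemic and mock cells, with 0 members past the test in limma. Phenylpropanoid synthesis genes, which supply lignin precursors, were lower in systemic cells, with 2 of 19 higher and a median of -0.57 (adjusted p = 0.0121; adjusted p = 0.585 with an estimated correlation). PAL (LOC4330034) differed by -1.16 ± 0.35 and HCT2 (LOC4329959) by -1.97 ± 0.74, both chosen after their values were seen. Ribosomal proteins had 19 of 25 genes higher and a median of 0.38, and photosynthesis genes 8 of 11 and a median of 1.03, each with adjusted p = 0.0132 and adjusted p = 0.75 with an estimated correlation. CAB2R (LOC4324599), a chlorophyll-binding protein gene chosen after its values were seen, was 2.48 ± 1.01 higher. The ribosomal call was lost without systemic 2 (adjusted p = 0.666), mock 1 (0.592) or mock 3 (0.105), the photosynthesis call without systemic 2 (0.506) or mock 2 (0.265), and the phenylpropanoid call without mock 1 (0.0741), mock 2 (0.0944) or systemic 3 (0.0971). The ribosomal mean was 8.71 on systemic 2, against 7.65 and 7.78 on the other systemic arrays. Random lists matched for level, drawn after the results were seen, had median changes of -0.16 for ribosomal proteins, -0.01 for photosynthesis and -0.09 for phenylpropanoid synthesis. The medians of these lists lay outside the central range of their random lists. For the xylem and sclerenchyma list the random lists had -0.11, and its median of -0.88 lay inside their central range, -0.91 to 0.54.

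**Figure D2:**
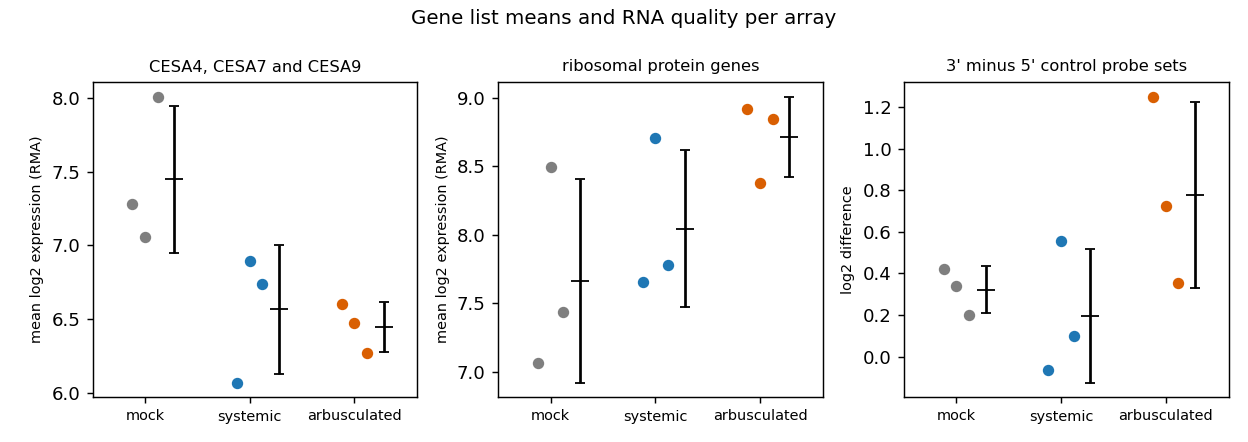
Mean log2 expression (RMA) of the 3 CESA genes and of the 25 ribosomal protein genes, and the 3' minus 5' difference (log2) of the rice controls, on each array by group. Coloured points are arrays and black bars the mean with the SD. The ribosomal mean was 8.50 on mock 2, against 7.06 and 7.44 on the other mock arrays.

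Across the 3 groups, 99 probe sets differed by the moderated F test. Of the probe sets higher in arbusculated cells, 76 were past the threshold over both mock and systemic cells, among them those of ILL8, CKI1, YSL13 and LOC4347898. Independent calls would share 0.237. Simulated data in which no group changed shared 0, but such data hold hardly any calls. They cannot show how many shared calls come from using the same arbusculated arrays in both contrasts. The changes of arbusculated and of systemic cells against mock correlated across probe sets at 0.213, while sharing the mock arrays alone gave 0.5 in 50 simulations. That value holds for unchanged groups only, so no conclusion is drawn from the difference. The F count was 12 without arbusculated 2, 20 without arbusculated 1, 22 without mock 1, 30 without mock 3, 47 without systemic 1, 55 without systemic 2 and 53 without systemic 3. The count of 76 was 18 without mock 1, 28 without mock 3, 20 without arbusculated 1, 34 without arbusculated 2, 28 without systemic 1, 29 without systemic 2 and 24 without systemic 3. With a replicate block these counts were 12 and 13, among the brighter probe sets 63 and 48, and the second was 7 with only the 6 arrays of each contrast and 49 with probe sets averaged per gene.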

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

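Of the tests in this part, those on the array of mock replicate 2, the xylem list and the ribosomal list were chosen only after the results were seen, while the comparisons with other splits of the arrays were chosen before.

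Arbusculated and systemic cells differed in their response against mock, with 141 probe sets past the test of the difference in limma, which is the contrast between both populations. All 10 splits of those 6 arrays were counted, the real value was 141 and the highest of the other splits 0, and 1 split was as large. For arbusculated against mock the real value was 107, the highest other 0, and 1 of 10 splits was as large. For systemic against mock the real value was 0, the highest other 0, and 10 of 10 splits were as large, with 2485 probe sets at an unadjusted p under 0.05 in limma. For the fixed gene lists the real values were 1, 1 and 0 for arbusculated against mock, systemic against mock and arbusculated against systemic, the highest others 2, 1 and 0, and 3, 2 and 10 of 10 splits were as large. These 10 splits are too few for a share under 0.05.

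Over 100 drawn splits of the 9 arrays, 4 gave as many probe sets by the F test as the real 99. The real split is among them, and the highest other gave 127. A share so near 0.05 in drawn splits does not exclude chance for the division into 3 groups. All 4 kept the arbusculated arrays together, 6 such splits were drawn, and splits that parted them gave at most 15. The F count thus rests on the arbusculated arrays standing apart. For probe sets higher in arbusculated cells than in both other groups, 1 of 100 splits, the real one, reached 76, the highest other being 68. Only 2 of the drawn splits set the arbusculated arrays apart, and the rest gave at most 1. A chance choice of the arrays set apart is argued against, while the division between mock and systemic arrays is not tested by this count.

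Control probe sets for fungal genes, which the comparisons did not use, were above every mock array on all 3 systemic arrays. The difference between systemic and mock means was 0.89 for ef1a-3_at, 0.67 for ef1a-3_x_at, 0.24 for ef1a-M_at, 0.38 for gapdh-5_at and 0.20 for gapdh-M_at. This held for 5 of the 10 controls, and the difference was not tested. In arbusculated cells 0 of the 10 were above every mock array, and ef1a-3_at differed by -0.45. These controls are labelled for another fungus, and whether they bind transcripts of the inoculated species is not given in the sources used here.

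The array of mock replicate 2 correlated more with the arbusculated arrays than with the other mock arrays on average, by 0.0249, which was 0.00806 without mock 1 and 0.0417 without mock 3. A swapped label is argued against by the responding probe set of PT11, at 3.87 on that array against 8.30 or more in arbusculated cells. A first test of a mixed sample gave mock 2 a median place of 0.413 between mock (0) and arbusculated (1) over 148 probe sets, against 0.182 to 0.19 on the systemic arrays, and a second test was chosen after that: the 13 probe sets at least 16-fold higher imply -0.0621% arbusculated RNA, against 25.8% on the other 135, which argues against a mixture. For the wider spread of values on that array, the excess was 0.0256 ± 0.0176 (SE over arrays) after quantile normalisation, which makes the spreads equal, and 0.0204 on ranks. The rule for this test was changed more than once after these values were seen, and an earlier version called the test void. The excess did not shrink after quantile normalisation, but it is small against its SE. Whether there is an excess to explain is thus itself uncertain, and no conclusion is drawn on the wider spread of mock 2. The 3' minus 5' difference of 0.341 on mock 2 lies between the other mock arrays (0.201 and 0.423), so this measure does not set it apart from them. It is below the lowest arbusculated array (0.357) by less than the SD of that group (0.45). This measure thus shows no sign of RNA quality shared with the arbusculated arrays but cannot exclude it. No biological explanation was tested.

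The xylem and sclerenchyma list was lower in arbusculated than in mock cells. With 3 further normalisations of the deposited values the highest adjusted p by camera was 0.00334. These were applied on top of the authors' normalisation, so they cannot exclude it as the cause. A single mock array as the cause is argued against by a highest adjusted p of 0.0376 with each left out. RNA of stele cells on the mock arrays could give the pattern and cannot be told apart, since 13 laccase and endodermis genes had a median of -0.0557 with members on both sides (7 lower). These lists leaned opposite ways, so their joint median describes neither. The 9 laccases had a median of -0.12 with 3 higher (adjusted p = 0.109 by camera). The 4 endodermis genes had a median of 0.56 with 3 higher (adjusted p = 0.609 by camera). The presence of the fungus, which the design names, stays open and untested, and the list's call was lost with an estimated correlation (adjusted p = 0.444). Systemic cells, which were free of the fungus, had a list median of -0.88 against mock. Between arbusculated and systemic cells the median was -0.08 (adjusted p = 0.739 by camera).

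Ribosomal protein genes were higher in arbusculated than in mock cells. A single mock array is argued against by a highest adjusted p of 0.0073 with each left out. A shift that depends on signal level as the whole cause is argued against by a list median at percentile 100 of 10000 random lists matched for level, 1.10 against 0.45, though such lists ignore how ribosomal genes vary together, and over systemic cells the list lay at percentile 70.5, at 0.76 against 0.69, where such a shift is not excluded. RNA quality may contribute and cannot be told apart, with a correlation of 0.368 between the deviations of both measures from their group means over 9 arrays. Variation from array to array stays open as well, since mock 2 had a mean of 8.50 against 8.38 on arbusculated 2 and the call was lost with an estimated correlation (adjusted p = 0.49), and the design's biological difference was not tested.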

How the results depend on the processing

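Of the tests in this part, cyclic loess, the lists from gene symbols, the symbol matching before its correction and the responding probe set of PT11 in the lists were chosen only after the data or results had been seen. ILL8 stayed past the threshold in the same direction in all 19 alternatives of both its contrasts (adjusted p 0.00253 to 0.0373 over mock and 0.0023 to 0.0438 over systemic cells). Over the 28 named results past the threshold, 329 of 520 alternatives kept the call, 191 lost it and 0 turned the direction. Of 30 named results short of the threshold, 1 passed it in an alternative.

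Counts that moved by over 1.5 times are given for arbusculated against mock, arbusculated against systemic, the F test and higher than both, in that order. The replicate block gave 32, 14, 12 and 13. Fits to 6 arrays, which have fewer samples, gave 44, 11 and, for higher than both, 7. Bright probe sets alone, which are fewer, gave 67 over mock, 63 by F and 48 for both. Averaging probe sets per gene, which tests genes, gave 66, 77 and, for both, 49. Trend and robust moderation gave 92 over systemic cells, and the cause was not tested.

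Leaving out 1 array gave 20 to 169 (without mock 1 and mock 2), 25 to 126 (without arbusculated 1 and mock 2), 12 to 113 (without arbusculated 2 and mock 2) and 18 to 75 (without mock 1 and arbusculated 3). Systemic against mock gave 0 to 3, highest without mock 2. The array left out leaves a group with fewer samples, and why arrays differed was not tested.

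The fixed lists past the threshold, 1, 1 and 0 in the contrasts over mock (arbusculated, systemic) and over systemic cells, were 0, 0 and 0 with an estimated correlation and with fry. Systemic against mock gave 0 with averaged probe sets and 0 to 1 with an array left out, 0 without mock 1, mock 3 or systemic 1. Lists from gene symbols gave 3, 3 and 5, and 3, 3 and 2 with the matching before its correction. The cause was not tested.

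Directions turned in some results that were short of the threshold as reported. Averaging turned PT11, by its representative, to 1.47 over mock and 1.18 over systemic cells, PT1 over systemic cells to -0.12 and AMT3;1 in systemic against mock to -0.00169. PT1 over systemic cells was also -0.10 after quantile normalisation, -0.0328 after cyclic loess, and -0.76 to 1.25 with an array left out. With an array left out PT2 over systemic cells ran from -0.24 to 0.51, and PT1 over mock from -0.0328 to 1.88. In systemic against mock PT1 ran from -0.48 to 1.80, PT6 from -1.19 to 0.56, PT7 from -0.0249 to 0.34, PT8 from -2.34 to 0.63 and PT12 from -0.055 to 0.18, and PT12 was -0.0233 after cyclic loess. The cause was not tested.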

Other observations

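Of the tests in this part, the test of neighbouring genes was chosen only after the results were seen.

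Markers that stood in lists too short to test gave the following values. The exodermal silicon channel Lsi1 was 0.73 ± 0.80 higher in arbusculated than in mock cells (adjusted p = 0.655), and the phloem sucrose transporter SUT1 0.08 ± 0.30 (adjusted p = 0.907). PBZ1 was 0.94 ± 0.60 higher (adjusted p = 0.46) and NH1 differed by -0.25 ± 0.95 (adjusted p = 0.906).

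The genes LOC4347897 and LOC4347898, among the largest rises, lie next to each other among the measured genes on assembly ASM3414082v1. Genes without a probe set were not considered, here or in the random sets. A hypothesis was that genes higher in arbusculated cells are neighbours more often than chance gives. It was not borne out, with 1 neighbouring pair among 63 genes against 0.212 on average in 10000 random sets (permutation p = 0.191).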
